A study of Mus musculus with 8 samples.

How the data were processed

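RNA sequencing was done on primary intestinal epithelial cells of wild-type C57BL/6 mice. Per the labels, cells were freed from the tissue with EDTA and DTT, RNA was purified and treated with DNase, ribosomal RNA was depleted, and TruSeq libraries were read single-end on an Illumina HiSeq. The series describes separate mice at each age within a tissue; whether both tissues came from the same mice, and the sex of the mice, are not given in the sources used here. The cells were not sorted, so that other cell types can be present.

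The authors deposited 1 table per library with estimated counts per transcript, per the file headers, beside transcript length and effective length. Per the submitters' processing notes the tools were CASAVA, bcl2fastq 2.17, cutadapt 1.1 and kallisto 0.43.0, with genome build GRCm38; settings and the annotation release are not given in the sources used here. Of the transcript values above 0, 14.9% had no fractional part as printed in the files, and effective length was the same in all files. The deposited estimated counts were not normalised. Each table held 96626 transcripts, of which 95301 (98.6%) matched a gene of GENCODE M21 by identifier; between 0.392 and 0.512% of a library's counts were in transcripts without a gene. Counts were summed over 32035 genes and rounded. Strand was not used, and counts of near-identical gene copies, pseudogenes and partners on the X and Y chromosomes rest on how the quantification divided shared reads. Totals per library ran from 11814156 to 24231151.

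Libraries were grouped by tissue and age from their titles. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 15844 genes with 99.96% of the counts, scaling was by TMM, and 1 model with 4 groups and 4 residual degrees of freedom was fitted by quasi-likelihood, with a common biological coefficient of variation of 0.445. The 5 contrasts were colon against small intestine, 8 against 4 weeks in small intestine, in colon and over both, and the difference of the age effects. Benjamini-Hochberg adjusted p below 0.05 was a call. With 2 libraries a group, the spread was shared over all genes and groups. Standard errors of single genes were derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. They are not standard errors of the fitted coefficient.

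A total of 35 gene lists with 614 entries was written from textbook knowledge: digestive enzymes of the brush border, fat absorption, transporters, iron with calcium and zinc, bile acids, colonic ion transport, posterior and proximal patterning, goblet, Paneth, enteroendocrine, tuft and stem cells, proliferation, antimicrobial defence, interferon-stimulated genes, cytokine receptors, innate sensors, MHC class II, suckling-type and adult-type enterocytes, circadian clock, cholesterol synthesis, fatty acid oxidation, xenobiotic metabolism, T, B and myeloid cells, stroma, neurons with glia, acinar and erythroid cells, immediate early genes, mitochondrial transcripts and sex-linked genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast; all 47 calls rest on the preset value.

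The contrasts, lists, alternative settings listed first below and the rule for named genes were chosen before the data were examined. The rule took, per contrast, up to 12 called genes with the largest change in each direction that had at least 5 CPM in the higher groups and no overlap between the sides, the 6 most abundant called genes per direction for the tissue contrast, and up to 4 members of each list by size of change. A gene with no count in 1 group of libraries is given as a bound against 3 counts over that group, and one with 1 to 3 counts as a ratio with an exact Poisson interval. Shares of counts have 95% Wilson intervals.

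Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 4 libraries, length-scaled counts, blocks by replicate number, single-tissue fits, an additive model and leaving out each library. Robust empirical Bayes, nuclear protein-coding genes without Lars2, leaving out the 8-week colon libraries, single-age contrasts and a crossed block were chosen after seeing the data. Recovery was tested on simulated data made from these counts. Shared stretches of Lars2 were searched with BLAST 2.17.0. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.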

Results

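RNA was sequenced from primary epithelial cells released from the small intestine or the colon of wild-type C57BL/6 mice aged 4 or 8 weeks. Each of the 4 combinations of tissue and age held 2 libraries, so that 8 libraries entered the comparisons. In small intestine, counts assigned to genes came to 16976300 and 11814156 in the 4-week replicates 1 and 2 and to 18389259 and 20430816 in the 8-week replicates. In colon they came to 17912316 and 24231151 at 4 weeks and to 22150299 and 22944327 at 8 weeks. Gene levels are given as CPM (counts scaled to library size after TMM normalisation), as mean ± SD. Changes of genes are given as log2 fold changes with a standard error (SE) derived from the F test. Intervals and lower bounds cover counting error only.

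The first principal component of the log2 CPM of all tested genes held 55.2% of the variance and placed the 4 small-intestine libraries between -118 and -84.8 and the 4 colon libraries between 85.3 and 109. The second held 10.4%. Replicates correlated across genes with r = 0.953 in small intestine at 4 weeks, 0.950 in small intestine at 8 weeks, 0.939 in colon at 4 weeks and 0.970 in colon at 8 weeks; genes are not independent replicates.

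The first comparison asked how epithelial cells of the colon differ from those of the small intestine, with 4 libraries against 4 and both ages averaged. Of 15844 genes tested, 2754 were higher and 2383 lower in colon, 5137 in all. Carbonic anhydrase 1, Car1 (chromosome 3, 14766216 to 14808368, GRCm38), measured 10205 ± 1233 CPM in colon and 0.117 ± 0.235 CPM in small intestine (n = 4 each, adjusted p = 3.39e-07). Sucrase-isomaltase, Sis, measured 5795 ± 1567 CPM in small intestine and 6.63 ± 2.71 CPM in colon, a log2 fold change of -9.76 (SE 0.46, adjusted p = 9.11e-07). The mucin of goblet cells, Muc2, rose from 2883 ± 907 CPM in small intestine to 11328 ± 1476 CPM in colon, a log2 fold change of 2.02 (SE 0.18, adjusted p = 2.84e-05). Under RLE scaling 49.8% of the called genes were higher in colon, against 53.6% under TMM.

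Genes of food digestion and uptake were lower in colon as groups. Of 18 brush border digestive enzymes 17 fell and 0 rose, with a median log2 fold change of -7.16 (list test adjusted p = 1.41e-15, adjusted p = 0.169 with an estimated correlation). Lactase, Lct, fell from 1831 to 1.75 CPM, a log2 fold change of -10.14 (SE 0.41), and enteropeptidase, Tmprss15, by a log2 fold change of -10.60 (SE 0.97), or -6.78 from the 8-week libraries alone. Enpp7, an alkaline sphingomyelinase, held 1 count over the 4 colon libraries, for a small-intestine to colon ratio of 18206 (95% interval 3267 to 719153). Of 19 genes of fat absorption and chylomicron assembly 17 fell and 2 rose, with a median of -6.85 (list test adjusted p = 5.24e-13, adjusted p = 0.169 with an estimated correlation). Among them were the cholesterol transporters Npc1l1 at -10.05 (SE 0.65) and Abcg8 at -9.52 (SE 0.24, with -7.63 from the 4-week and -11.41 from the 8-week libraries alone), and the apolipoprotein gene Apoa1 at -9.20 (SE 0.39). Apoc3 had no colon count and was at least 906-fold lower there. All 18 transporters of sugars, amino acids and vitamins fell, with a median of -5.08 (list test adjusted p = 1.37e-15, adjusted p = 0.169 with an estimated correlation), the glucose and fructose transporter Slc2a2 by -9.80 (SE 0.48) and the neutral amino acid transporter Slc6a19 by -8.95 (SE 0.49). Adjusted over the list alone, the enzymes had 1 higher and 17 lower, the fat genes 2 and 17, and the transporters 0 and 18.

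Other absorptive groups were mixed. Of 9 genes of bile acid transport and FXR targets 5 fell and 2 rose, or 6 and 2 adjusted over the list alone, with a median of -2.07 (list test adjusted p = 0.0142, adjusted p = 0.340 with an estimated correlation). The organic anion exporter Abcc2 fell by a log2 fold change of -8.12 (SE 0.48) and the ileal bile acid binding protein gene Fabp6 by -7.34 (SE 0.95). Of 15 genes of iron, calcium and zinc handling 7 rose and 2 fell, 8 and 2 adjusted over the list alone, with a median of 0.72 and no list call (adjusted p = 0.321). Calbindin-D9k, S100g, rose by 3.51 (SE 0.34), with 1.76 from the 4-week libraries alone and 5.26 from the 8-week libraries alone. Of 9 adult-type enterocyte genes 7 fell and 2 rose by either adjustment, with a median of -3.64 (list test adjusted p = 0.00411, adjusted p = 0.340 with an estimated correlation), among them trehalase, Treh, at -8.23 (SE 0.71). Of 16 suckling-type enterocyte genes 5 rose and 7 fell by either adjustment, with a median of -0.29 (adjusted p = 0.190).

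Colonic ion and water transport genes were higher in colon, with 14 of 16 risen and 1 fallen, 15 and 1 adjusted over the list alone, and a median of 3.25 (list test adjusted p = 1.34e-07, adjusted p = 0.169 with an estimated correlation). The water channel gene Aqp8 rose from 3.16 ± 2.52 to 220 ± 55.4 CPM. The potassium pump gene Atp12a and the sodium channel subunit gene Scnn1b had no small-intestine count and were at least 594-fold and 142-fold higher in colon. Of 8 posterior patterning transcription factors 7 rose and 1 fell by either adjustment, with a median of 7.40, or 5.99 with genes at zero counts set to their bound (list test adjusted p = 2.17e-04, adjusted p = 0.169 with an estimated correlation). Hoxb13, Hoxa13, Hoxa11 and Hoxd8 were at least 459-fold, 205-fold, 89.2-fold and 55.3-fold higher in colon. Of 12 proximal patterning transcription factors 8 fell and 1 rose, 9 and 2 adjusted over the list alone, with a median of -4.64 (list test adjusted p = 3.63e-04, adjusted p = 0.169 with an estimated correlation). Gata4 fell by -8.21 (SE 0.45), Onecut2 fell by -7.96 (SE 0.38), and Pdx1 was at least 94.8-fold lower.

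Markers of secretory cells split by cell type. Of 18 goblet cell genes 14 rose and 2 fell by either adjustment, with a median of 2.07 (list test adjusted p = 9.78e-06, adjusted p = 0.340 with an estimated correlation). The goblet factors Agr2 and Spdef rose by 3.25 (SE 0.36) and 3.02 (SE 0.24), and Best2 was at least 96.5-fold higher. The resistin-like gene Retnlb measured 169 ± 53.0 CPM in colon and 0.235 ± 0.470 CPM in small intestine. Of 18 Paneth cell genes 15 fell and 2 rose by either adjustment, with a median of -8.73, or -8.66 with genes at zero counts set to their bound (list test adjusted p = 4.23e-08, adjusted p = 0.169 with an estimated correlation). The alpha-defensin genes are near-identical copies, so that counts shared among them leave single members uncertain. Defa20 had a small-intestine to colon ratio of 2250 (95% interval 403 to 88928). Of 19 enteroendocrine genes 4 rose and 5 fell by either adjustment, with a median of -0.77 (adjusted p = 0.422). Among them Gip was at least 605-fold lower and Insl5 at least 115-fold higher in colon. None of 17 tuft cell genes was called by edgeR by either adjustment (median -0.42, adjusted p = 0.422), and Pou2f3 had a log2 fold change of 2.10 (SE 0.75, adjusted p = 0.0571).

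Stem cell markers went both ways, with 5 of 16 higher and 3 lower by either adjustment; the list's median was 0.35, its mean -0.29 and its test pointed up (adjusted p = 0.575). Olfm4 fell from 479 to 0.559 CPM, a log2 fold change of -10.48 (SE 0.56), while Prom1 rose by 2.28 (SE 0.18) and Ephb2 by 1.67 (SE 0.20). Of 20 proliferation genes 10 rose and 0 fell, 11 and 0 adjusted over the list alone, with a median of 0.58 (list test adjusted p = 0.0129, adjusted p = 0.736 with an estimated correlation). The proliferation call was lost without small-intestine 8-week replicate 2 (adjusted p = 0.0855) or colon 4-week replicate 1 (adjusted p = 0.0612), and without the 8-week colon libraries none of the 20 genes was called, although their median was then 0.64.

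Defence and sensing genes differed gene by gene. Of 19 antimicrobial and mucosal defence genes 8 rose and 7 fell, 8 and 8 adjusted over the list alone (median -0.31, adjusted p = 0.472). Reg1 and Reg3a fell by -7.52 (SE 0.46) and -6.93 (SE 0.52) and lactoperoxidase, Lpo, was at least 475-fold higher in colon. Of 27 innate sensor and inflammasome genes 11 rose and 7 fell, 11 and 8 adjusted over the list alone; their median was -0.04, their mean 0.56 and their test pointed up (adjusted p = 0.744). The lipopolysaccharide receptor gene Tlr4 rose by 5.44 (SE 0.32) and the DNA sensor gene Aim2 by 3.48 (SE 0.21). Of 15 interferon and cytokine receptor genes 2 rose and 6 fell, 2 and 8 adjusted over the list alone, with a median of -0.61 (list test adjusted p = 0.0129, adjusted p = 0.509 with an estimated correlation). Il1r1 rose by 6.84 (SE 0.54) and Tnfrsf1a fell by -1.72 (SE 0.20). Of 30 interferon-stimulated genes 7 rose and 1 fell, 6 and 0 adjusted over the list alone (median 0.55, adjusted p = 0.427). Of 27 MHC class II and interferon-gamma target genes 14 fell and 4 rose, 15 and 4 adjusted over the list alone, with a median of -0.60 (list test adjusted p = 0.00882, adjusted p = 0.670 with an estimated correlation). The antigen presentation genes H2-Aa and Cd74 fell by -3.45 (SE 0.41) and -2.67 (SE 0.37), with H2 genes uncertain where copies share sequence. The MHC class II call was lost without colon 4-week replicate 2 (adjusted p = 0.0909), and without the 8-week colon libraries 10 of these genes were lower and 1 higher.

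Metabolic groups also differed. Of 22 cholesterol synthesis genes 14 rose and 2 fell, 15 and 2 adjusted over the list alone, with a median of 0.97 (list test adjusted p = 3.96e-04, adjusted p = 0.509 with an estimated correlation), among them the mevalonate pathway genes Mvd at 2.22 (SE 0.25) and Fdft1 at 1.98 (SE 0.20). Of 26 xenobiotic metabolism genes 15 fell and 6 rose, 16 and 6 adjusted over the list alone, with a median of -1.19 (list test adjusted p = 5.34e-04, adjusted p = 0.509 with an estimated correlation). Cyp2b10 had no colon count, was at least 5933-fold lower there and measured 186 ± 16.9 CPM in small intestine; reads shared among Cyp2b and Cyp3a copies leave single members uncertain. Of 21 genes of fatty acid oxidation and PPAR targets 8 rose and 5 fell by either adjustment; their median was 0.24, their mean -0.27 and their test pointed down (adjusted p = 0.968). Of 18 circadian clock genes 6 fell and 0 rose by either adjustment (median -0.04, adjusted p = 0.351), and without the 8-week colon libraries 1 was lower.

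Markers of other cell types were lower in colon for T cells and not called as lists for the rest. Of 21 T cell and intraepithelial lymphocyte genes 12 fell and 0 rose, 14 and 0 adjusted over the list alone, with a median of -1.52 (list test adjusted p = 1.54e-05, adjusted p = 0.169 with an estimated correlation). The granzyme genes Gzma and Gzmb fell by -3.20 (SE 0.30) and -2.68 (SE 0.19). None of 11 B cell and plasma cell genes was called by edgeR (median -0.67, adjusted p = 0.422). Of 13 myeloid genes 1 rose and 2 fell (median -0.79, adjusted p = 0.351), and of 13 stromal, endothelial and muscle genes 1 rose and 1 fell, 1 and 0 adjusted over the list alone (median 0.32, adjusted p = 0.586). None of 4 enteric neuron and glia genes was called (median 0.35, adjusted p = 0.586). Of 9 pancreatic acinar genes 1 rose; their median was -0.31, their mean 0.08 and their test pointed down (adjusted p = 0.909). None of 5 erythroid genes was called; their median was -0.32, their mean 0.77 and their test pointed down (adjusted p = 0.718). Except for the stromal list, the counts adjusted over the list alone matched for these marker lists of B cells, myeloid cells, neurons, acinar and erythroid cells.

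Groups that follow tissue handling or library make-up were measured beside these. Of 17 dissociation and immediate early response genes 8 rose and 2 fell, 10 and 2 adjusted over the list alone (median 0.85, adjusted p = 0.0647). Hspa1b rose by 2.57 (SE 0.35). Of 13 mitochondrially encoded genes 1 rose and 3 fell by either adjustment (median -0.27, adjusted p = 0.426). Lars2, a mitochondrial leucyl-tRNA synthetase gene, was the most abundant called gene, with a log2 fold change of -3.66 (SE 0.75, adjusted p = 0.00476). It held 11.4% (95% Wilson interval 11.4 to 11.5), 14.0% (14.0 to 14.0), 8.00% (7.99 to 8.02) and 4.26% (4.25 to 4.27) of the counts of the small-intestine libraries. In colon it held 1.33% (1.33 to 1.34), 0.0601% (0.0591 to 0.0611), 1.14% (1.14 to 1.15) and 0.844% (0.840 to 0.848). With the 8-week libraries alone the Lars2 call was lost (log2 fold change -2.75, adjusted p = 0.0975). All 4 tested sex-linked genes, which lie on the Y chromosome, fell in colon by either adjustment, with a median of -2.50 (list test adjusted p = 0.00472, adjusted p = 0.470 with an estimated correlation); without the 8-week colon libraries none of the 4 was called and their median was -0.24.

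**Figure D1:**
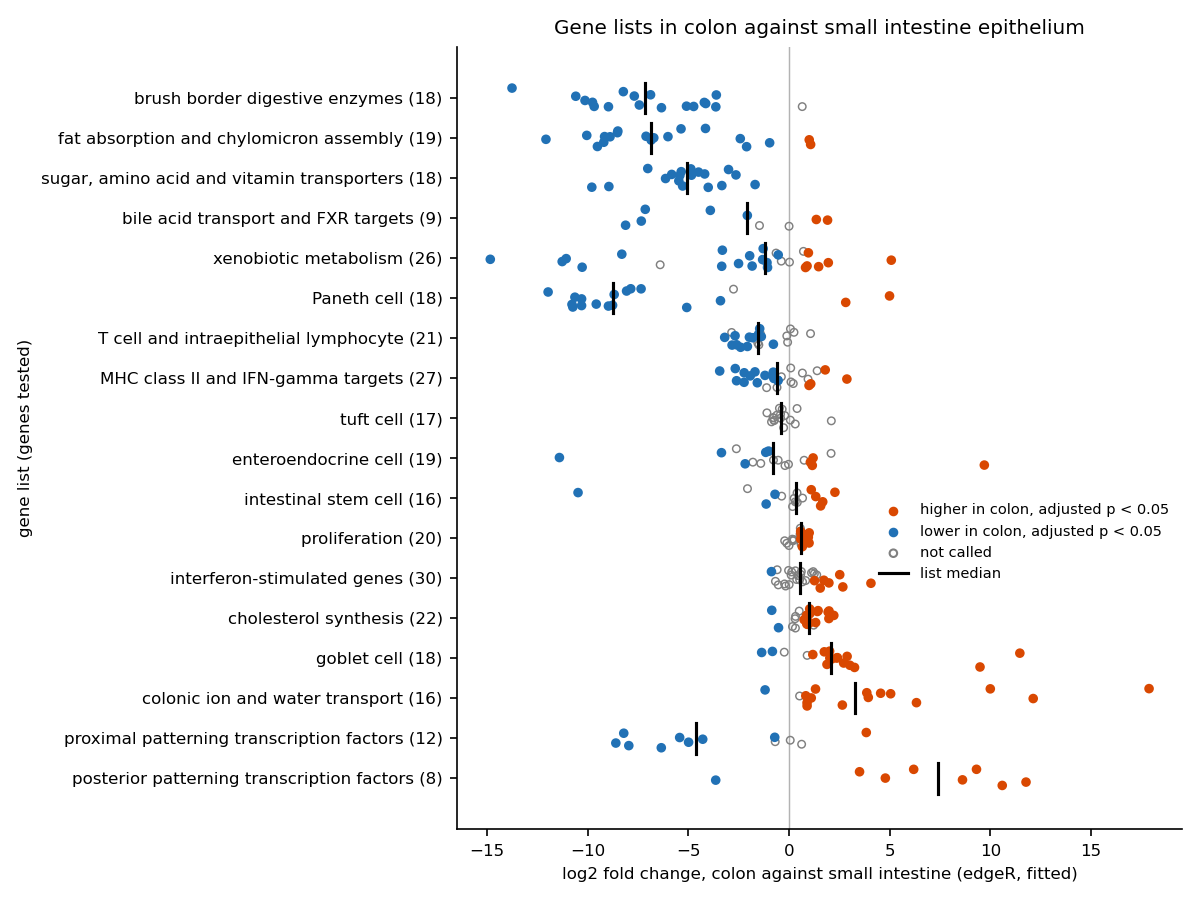
Log2 fold change in colon against small intestine (x axis) of each tested member of 18 gene lists (y axis), with the list median as a marker; n = 4 libraries per tissue. Brush border enzymes have a median of -7.16 and colonic ion and water transport genes a median of 3.25.

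**Figure D2:**
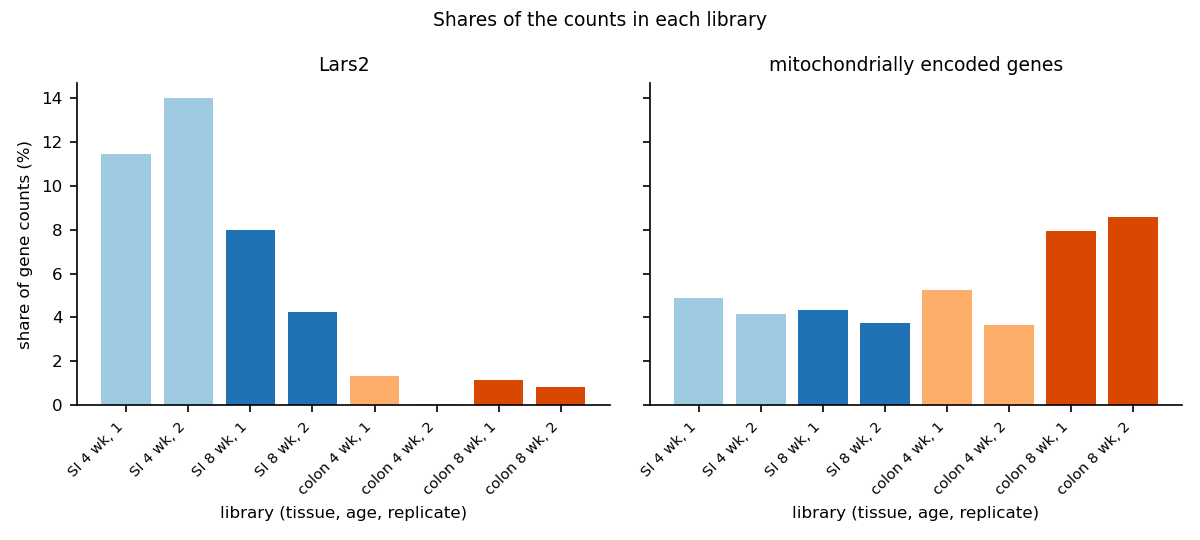
Percent of each library's gene counts in Lars2 and in mitochondrially encoded genes (y axes from 0), 1 bar per library. Lars2 holds 4.26 to 14.0% in the small-intestine libraries and at most 1.33% in the colon libraries.

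The tissue count stood at 2908 genes without the 8-week colon libraries, 3028 with the 4-week libraries alone and 2767 with the 8-week libraries alone. No list call of this or any later comparison held with an estimated correlation.

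The second comparison asked which genes differ between 8 and 4 weeks in small intestine, with 2 libraries against 2. S100g, the vitamin D responsive calcium-binding protein calbindin-D9k (chromosome X, 162961992 to 162964599), was the 1 gene called and was lower at 8 weeks. It measured 62.5 and 113 CPM in the 4-week libraries and 1.68 and 1.54 CPM in the 8-week libraries, a log2 fold change of -5.76 (SE 0.54, adjusted p = 0.0226). The iron exporter gene Slc40a1 measured 288 ± 12.6 CPM at 4 weeks and 49.4 ± 20.5 CPM at 8 weeks (n = 2 each), a log2 fold change of -2.54 (SE 0.34) that did not pass (adjusted p = 0.129). The calcium channel gene Trpv6 had -3.43 (SE 0.92, adjusted p = 0.560). Without small-intestine 8-week replicate 2 the S100g call was lost, with a log2 fold change of -5.70. Over 18 alternatives its adjusted p ran from 3.82e-59 to 0.640.

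Of 35 lists, 4 passed the list test in small intestine. Of the 15 genes of iron, calcium and zinc handling 1 fell, 3 adjusted over the list alone, with a median of -0.33 (adjusted p = 0.0228, adjusted p = 0.630 with an estimated correlation). That call was lost without 4-week replicate 1 (adjusted p = 0.144) or 8-week replicate 1 (adjusted p = 0.124) of small intestine. The 21 T cell and intraepithelial lymphocyte genes had a median of 1.18 (adjusted p = 6.28e-05, adjusted p = 0.630 with an estimated correlation), with none called over all genes and 6 higher adjusted over the list alone. Nkg7 and Ccl5 had 1.73 (SE 0.49, adjusted p = 0.599) and 1.67 (SE 0.70, adjusted p = 0.688). The 17 tuft cell genes had a median of 0.64 (adjusted p = 0.0228, adjusted p = 0.819 with an estimated correlation) and none called by either adjustment; the call was lost without 4-week replicate 2 (adjusted p = 0.592) or 8-week replicate 2 (adjusted p = 0.525). The 17 immediate early genes had a median of 0.81 (adjusted p = 0.00102, adjusted p = 0.819 with an estimated correlation), with none called and 4 higher adjusted over the list alone. Fosb had 2.64 (SE 0.46, adjusted p = 0.385), and the immediate early call was lost without 8-week replicate 2 (adjusted p = 0.176). The suckling-type enterocyte list was not called (median -0.09, adjusted p = 0.283), nor was the adult-type list (median 0.10). None of 18 clock genes was called over all genes and 3 were higher adjusted over the list alone. Dbp had 7.47 (SE 1.68, adjusted p = 0.560). The mean log2 CPM of the clock list was 3.11 and 3.48 at 4 weeks, and 3.57 and 4.79 in 8-week replicates 1 and 2. The higher mean at 8 weeks thus lay mainly in replicate 2.

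By edgeR 1134 genes had an unadjusted p below 0.05 here. The count of 1 became 74 by DESeq2, 3 by limma-voom and 315 without a low-count filter. It became 7, 3, 16 and 0 without small-intestine 4-week replicates 1 and 2 and 8-week replicates 1 and 2, and 3, 3, 2 and 3 without the corresponding colon libraries.

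The third comparison asked the same of colon, again 2 libraries against 2. Itgae (chromosome 11, 73090583 to 73147446), the CD103 integrin of intraepithelial lymphocytes, rose from 4.25 and 2.82 CPM at 4 weeks to 21.9 and 22.9 CPM at 8 weeks, a log2 fold change of 2.67 (SE 0.36, adjusted p = 0.0493). Ptprc (chromosome 1, 138062861 to 138175708), the pan-leukocyte marker CD45, rose from 20.0 and 17.9 to 63.8 and 98.9 CPM (log2 fold change 2.10, SE 0.28, adjusted p = 0.0493). Itln1 (chromosome 1, 171518122 to 171535294), a lectin of Paneth and goblet cells, rose from 0.742 and 2.93 to 33.4 and 46.2 CPM (log2 fold change 4.39, SE 0.57, adjusted p = 0.0493). Abcg8 (chromosome 17, 84676302 to 84700333), a sterol exporter gene, fell from 56 counts at 4 weeks to 3 counts at 8 weeks, a ratio of 18.6 (95% interval 6.05 to 93.0, adjusted p = 0.0305). In the same comparison the 4 sex-linked genes fell: Ddx3y, Uty, Eif2s3y and Kdm5d had log2 fold changes of -4.70 (SE 0.52), -4.35 (SE 0.48), -5.30 (SE 0.65) and -2.06 (SE 0.24).

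In all, 9 genes were called in colon by edgeR, 4 higher and 5 lower (44.4% higher), and under RLE scaling 6, of which 1 was higher (16.7%). The fourth gene that rose, Rps15a-ps6, is a ribosomal protein pseudogene, whose counts are uncertain because sharing of reads with similar genes was not measured. It was chosen after its values were seen, had 0 counts at 4 weeks and was at least 49.8-fold higher at 8 weeks. Leaving out 1 library ended the Itgae call for 5 libraries, with adjusted p of 0.0606 and 0.0545 without small-intestine 4-week replicates 1 and 2, 0.0827 without colon 4-week replicate 2, and 0.0641 and 0.128 without colon 8-week replicates 1 and 2. The Ptprc call ended without small-intestine 8-week replicate 1 (0.0552) or 2 (0.0542), colon 4-week replicate 1 (0.0617) or 2 (0.0823) and colon 8-week replicate 2 (0.226). The Itln1 call ended without small-intestine 8-week replicate 1 (0.0546) or colon 8-week replicate 2 (0.0698), and the Abcg8 and Kdm5d calls without colon 8-week replicate 1 (0.0782 and 0.0504) or 2 (0.0963 and 0.219). The highest adjusted p over all 18 alternatives was 0.178 for Itgae, 0.226 for Ptprc, 0.225 for Itln1, 0.547 for Abcg8 and 0.219 for Kdm5d, and the lowest was 1.07e-11, 1.22e-10, 1.36e-40, 8.20e-11 and 3.31e-12. With replicate number as a block the Itgae (adjusted p = 0.0842), Itln1 (0.0800) and Ptprc calls ended. Fitting colon alone ended the Ddx3y, Uty and Eif2s3y calls (adjusted p = 0.178 each), and the Eif2s3y call also ended with length-scaled counts (0.195) and robust empirical Bayes (0.123). Over 18 alternatives the lowest adjusted p of these 3 genes was 2.03e-45, 6.24e-40 and 1.09e-53.

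Of 35 lists, 9 passed in colon. Of the 21 T cell and intraepithelial lymphocyte genes 2 rose and 0 fell, 13 and 0 adjusted over the list alone, with a median of 1.71 (adjusted p = 3.79e-18, adjusted p = 0.144 with an estimated correlation). Other members with large changes were Trac at 2.94 (SE 0.82, adjusted p = 0.518) and Ccl5 at 2.84 (SE 0.74, adjusted p = 0.447). The 8-week libraries in which Itgae and Ptprc were higher are those with low Y-linked genes, whose 4 members fell with a median of -4.52 (adjusted p = 5.71e-10, adjusted p = 0.274 with an estimated correlation), also 4 adjusted over the list alone. None of 13 mitochondrially encoded genes was called over all genes and 9 were higher adjusted over the list alone, with a median of 0.87 (adjusted p = 2.84e-07, adjusted p = 0.274 with an estimated correlation). Their share of the counts was 5.24% (95% Wilson interval 5.23 to 5.25) and 3.66% (3.65 to 3.67) in the 4-week colon libraries and 7.95% (7.94 to 7.96) and 8.55% (8.54 to 8.56) in the 8-week ones. Of 18 Paneth cell genes 1 rose, 3 adjusted over the list alone, with a median of 0.75 (adjusted p = 0.00701, adjusted p = 0.670 with an estimated correlation). The 1 called was Itln1, also a goblet cell gene. Mean levels of the list in colon were low, at -1.70 and -1.64 log2 CPM at 4 weeks and -0.92 and -0.57 at 8 weeks. Several of its alpha-defensin genes had 0 or 1 counts over the colon libraries. None of 17 tuft cell genes was called and 2 were higher adjusted over the list alone, with a median of 1.25 (adjusted p = 4.61e-06, adjusted p = 0.638 with an estimated correlation). Alox5 had 1.82 (SE 0.65, adjusted p = 0.686).

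The other 4 lists past the test in colon had no gene called by either adjustment. They were B cell and plasma cell genes (median 1.94, adjusted p = 0.00229, adjusted p = 0.638 with an estimated correlation), MHC class II and interferon-gamma targets (median 0.65, adjusted p = 1.84e-05, adjusted p = 0.686 with an estimated correlation), interferon-stimulated genes (median 0.09, adjusted p = 0.00435, adjusted p = 0.943 with an estimated correlation) and cholesterol synthesis (median 0.27, adjusted p = 0.0438, adjusted p = 0.876 with an estimated correlation). Jchain had 2.26 (SE 0.82, adjusted p = 0.694), H2-Aa 1.65 (SE 0.55, adjusted p = 0.650), Bst2 1.04 (SE 0.57, adjusted p = 0.856) and Fdft1 0.83 (SE 0.27, adjusted p = 0.614). Without colon 4-week replicate 2 the MHC class II call was lost (adjusted p = 0.460) and the interferon-stimulated list pointed down (adjusted p = 5.41e-06). Mean levels of that list were 6.19 and 3.68 log2 CPM in the 4-week and 5.55 and 5.59 in the 8-week colon libraries. Without colon 8-week replicate 2 the interferon-stimulated and B cell calls were lost (adjusted p = 0.0508 and 0.138), and leaving out any of 5 libraries ended the cholesterol call (adjusted p = 0.0530 to 0.517).

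In colon 1000 genes had an unadjusted p below 0.05. The count of 9 became 140 by DESeq2, 18 by limma-voom, 326 without a low-count filter, 0 with the 4 colon libraries alone, and 27 and 32 without colon 4-week replicates 1 and 2.

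**Figure D3:**
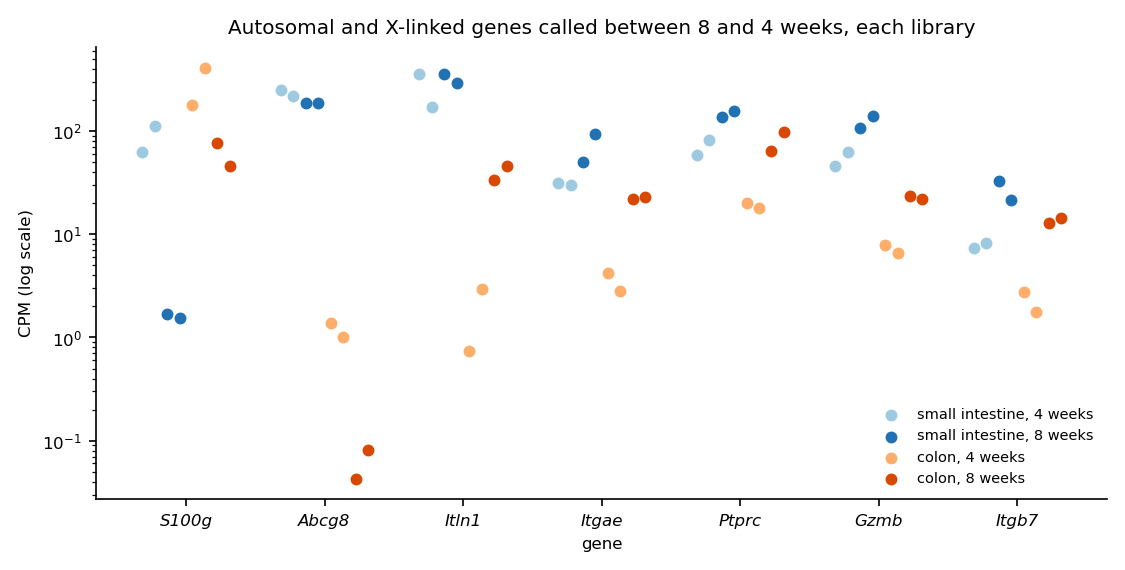
CPM (log axis) of 7 genes called in an age comparison, 1 point per library, by tissue and age (n = 2 each). S100g is 1.68 and 1.54 CPM in the 8-week small-intestine libraries and 46.0 to 415 CPM in the colon libraries.

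The fourth comparison averaged the age difference over both tissues, with 4 libraries against 4. S100g fell (log2 fold change -4.01, SE 0.35, adjusted p = 0.0109) and so did Abcg8 (-2.22, SE 0.25, adjusted p = 0.0470) and Uty (-2.40, SE 0.31, adjusted p = 0.0470). The averaged Abcg8 value comes mainly from the 3 counts in 8-week colon. The averaged Uty value also comes mainly from colon, with -4.35 (SE 0.48) there and -0.45 (SE 0.41) in small intestine. In small intestine Abcg8 measured 253 and 220 CPM at 4 weeks and 189 and 186 CPM at 8 weeks, and an additive model of tissue and age gave -1.06 (adjusted p = 0.528, 7.00e-10 to 0.528 over 18 alternatives). Itgb7 (chromosome 15, 102215995 to 102231944), the integrin subunit that pairs with the Itgae product, rose by 2.20 (SE 0.27, adjusted p = 0.0470), from 7.38 and 8.28 to 33.2 and 21.7 CPM in small intestine and from 2.77 and 1.77 to 12.9 and 14.5 CPM in colon. Itgae, Ptprc and the granzyme gene Gzmb (chromosome 14, 56258838 to 56262260), chosen after their values were seen, rose by 1.94 (SE 0.24), 1.59 (SE 0.19) and 1.43 (SE 0.18), each with adjusted p = 0.0470. These 7 genes, 4 higher and 3 lower (57.1% higher), were all that passed by edgeR; under RLE scaling 1 passed and 0% were higher.

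Of 35 lists, 9 passed over both tissues. Of the 21 T cell and intraepithelial lymphocyte genes 3 rose and 0 fell, 14 and 0 adjusted over the list alone, with a median of 1.43 (adjusted p = 1.20e-14, adjusted p = 0.212 with an estimated correlation). The mean log2 CPM of this list was 2.56 and 2.70 in small intestine at 4 weeks and 3.21 and 3.83 at 8 weeks. Of the 15 iron, calcium and zinc genes 1 fell, 4 adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00881, adjusted p = 0.448 with an estimated correlation). Trpv6 had -4.18 (SE 0.61, adjusted p = 0.0552). The sex-linked genes had a median of -2.42 with 1 lower, 4 adjusted over the list alone (adjusted p = 5.38e-07, adjusted p = 0.448 with an estimated correlation). The tuft, Paneth, goblet and B cell lists had medians of 0.98 (adjusted p = 9.18e-06), 0.95 (adjusted p = 0.00664), 0.33 (adjusted p = 0.00700) and 1.54 (adjusted p = 0.00911), each with adjusted p = 0.575 with an estimated correlation. None of their genes was called over all genes, and adjusted over the list alone the counts higher and lower were 3 and 0, 2 and 0, 3 and 1, and 2 and 0. The MHC class II list had a median of 0.42 (adjusted p = 0.00911, adjusted p = 0.750 with an estimated correlation) with none called by either adjustment, and the immediate early list 0.41 (adjusted p = 0.0325, adjusted p = 0.641 with an estimated correlation) with none called and 3 higher adjusted over the list alone.

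Leaving out 1 library ended several of these calls: iron without small-intestine 4-week replicate 1 (adjusted p = 0.0868), goblet without small-intestine 4-week replicate 2 (adjusted p = 0.259), Paneth without small-intestine 8-week replicate 1 (adjusted p = 0.345), and B cell without small-intestine 8-week replicate 2 (adjusted p = 0.0876) or colon 8-week replicate 2 (adjusted p = 0.0666). The MHC class II call ended without small-intestine 4-week replicate 1 (adjusted p = 0.138), colon 4-week replicate 2 (adjusted p = 0.793) or colon 8-week replicate 2 (adjusted p = 0.0752), and the immediate early call held under 3 of 10 alternatives. The gene count of 7 became 16, 2, 26 and 0 without small-intestine 4-week replicates 1 and 2 and 8-week replicates 1 and 2, 24 and 44 without colon 4-week replicates 1 and 2, and 13 without colon 8-week replicate 1. It became 213 by DESeq2, 13 by limma-voom and 494 without a low-count filter, with 1596 genes at an unadjusted p below 0.05. An additive model of tissue and age called 0. Replicate number as a block ended the Itgb7, Abcg8 and Uty calls. The S100g call ended without small-intestine 8-week replicate 2 (adjusted p = 0.0794) and held under 15 of 18 alternatives (1.59e-70 to 0.234). The Itgb7 call held under 10 of 18 (6.38e-09 to 0.128) and ended without small-intestine 4-week replicate 1 (0.0586) or 2 (0.110), small-intestine 8-week replicate 2 (0.0794) or colon 8-week replicate 2 (0.0672). The Abcg8 call held under 9 of 18 (7.00e-10 to 0.528) and ended without replicate 2 of small intestine at 4 (0.0767) or 8 weeks (0.0794) or colon 8-week replicate 1 (0.0701) or 2 (0.0739). The Uty call held under 12 of 18 (1.19e-28 to 0.463) and ended without replicate 2 of small intestine at 4 (0.110) or 8 weeks (0.105).

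**Figure D4:**
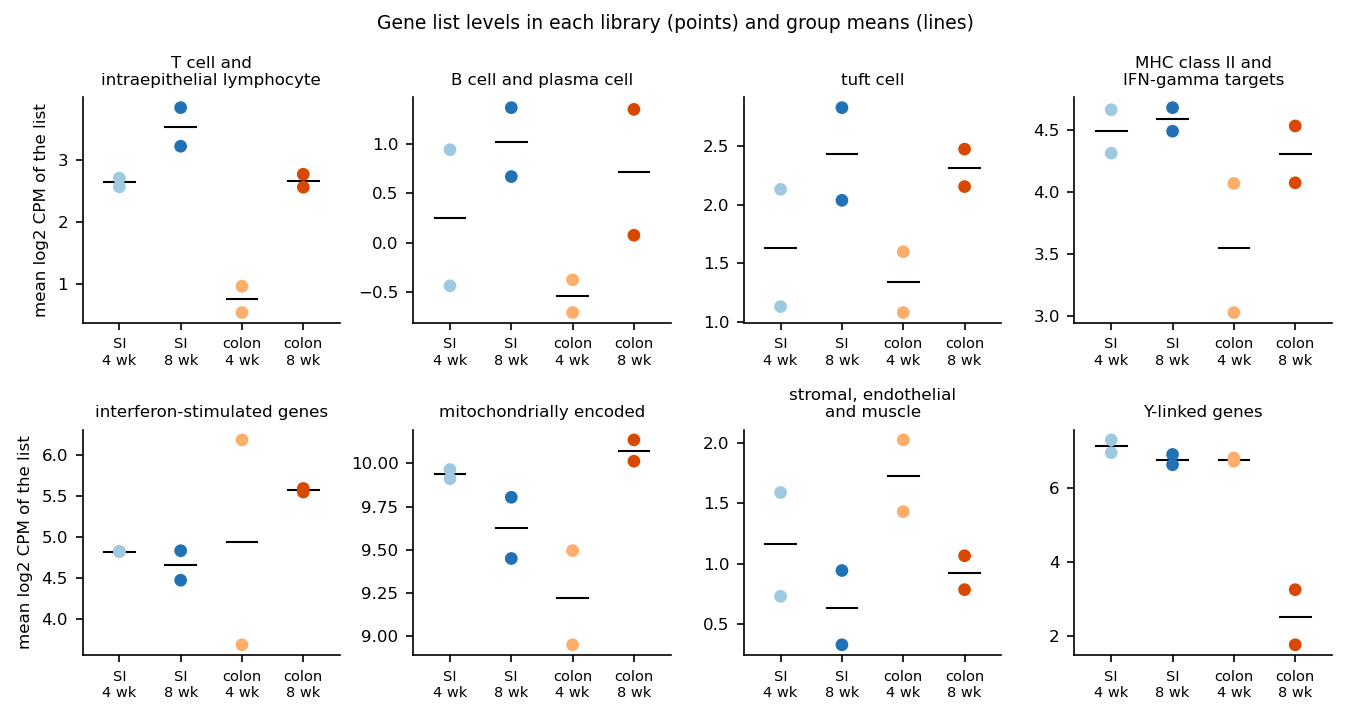
Mean log2 CPM of 8 gene lists (y axis) in each library, by tissue and age (n = 2 each). The T cell list lies at 2.56 and 2.70 at 4 weeks and at 3.21 and 3.83 at 8 weeks in small intestine.

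The fifth comparison tested whether the age difference itself differed between colon and small intestine. By edgeR it called 0 genes, with a lowest adjusted p of 0.227 and 806 genes at an unadjusted p below 0.05. DESeq2 called 65, limma-voom 0 and edgeR without a low-count filter 283. S100g had an interaction of 3.50 (SE 0.65, adjusted p = 0.399) and Itln1 of 4.08 (SE 0.72, adjusted p = 0.335), so that the calls made in 1 tissue are not shown to be absent from the other. The count became 1 without small-intestine 4-week replicate 1, 6 and 7 without colon 4-week replicates 1 and 2, and 5 and 4 without colon 8-week replicates 1 and 2. Across the 15844 genes the age changes of the 2 tissues, which share no library, correlated with r = 0.0704 and rho = 0.157, and with r = 0.188 and rho = 0.270 across the 8913 genes with a mean of at least 10 CPM; genes are not independent replicates.

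The 8-week colon libraries stood apart in sex-chromosome genes. Eif2s3y measured 104 and 82.9 CPM in the 4-week and 3.94 and 0.817 CPM in the 8-week colon libraries, against 74.6 to 183 CPM in small intestine. The 4 Y-linked genes kept 3.86% (Ddx3y), 2.55% (Eif2s3y), 4.92% (Uty) and 23.9% (Kdm5d) of their 4-week colon level. Their X-linked partner Eif2s3x measured 183 and 184 CPM at 4 weeks and 374 and 323 CPM at 8 weeks in colon, a log2 fold change of 0.93 (SE 0.22, adjusted p = 0.369). Genes of the X and Y copies resemble each other, so that small residual counts may be shared. The sex-linked list named Xist, but it was not among the genes tested, so that this female marker could not be used. For 43 library measures compared between tissues by exact two-sided permutation, the smallest p that 4 against 4 allows, 0.0286, corresponded to an adjusted p of 0.0683, and none passed. The matching permutation for age ignored tissue, and no result for age is drawn from it.

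**Figure D5:**
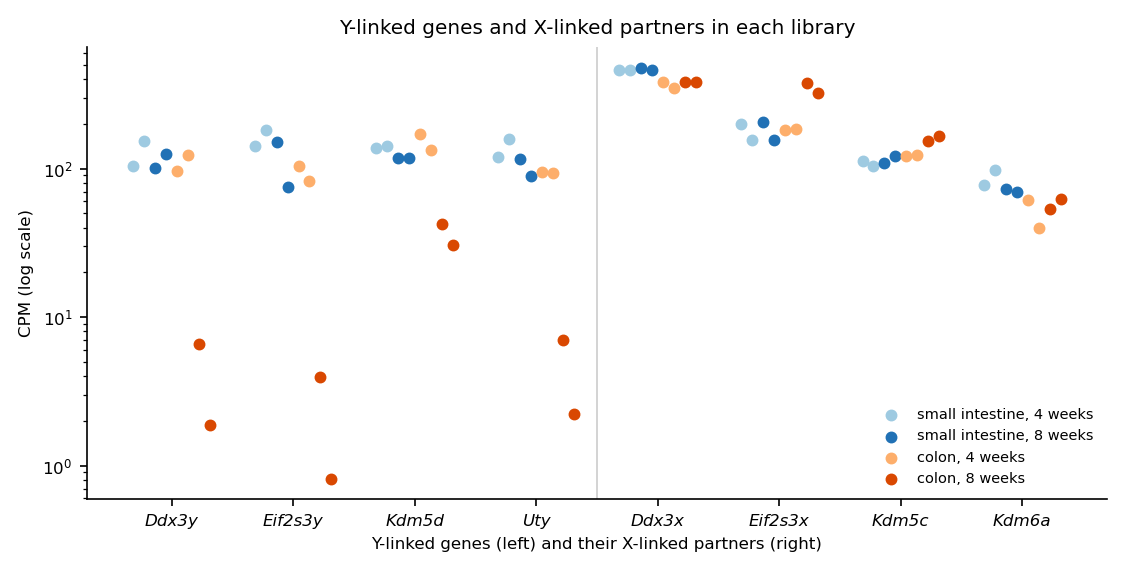
CPM (log axis) of 4 Y-linked genes and their 4 X-linked partners, 1 point per library, by tissue and age (n = 2 each). Eif2s3y is 3.94 and 0.817 CPM in the 8-week colon libraries and at least 74.6 CPM in the other libraries.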

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

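All tests weighed here were chosen after the result was seen, except those of the X-linked partners, of the mitochondrial synthetases and of the other tissue splits; the library measures and list interactions were planned.

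In 2 of 86 groups of 4 libraries screened, 1 library lay far from the other 3 of its tissue (ratio of gap to range, 0.970 and 0.888), which chance gives in about 1 in 20 groups. Small-intestine 8-week replicate 1 had a mean of 4.47 log2 CPM for interferon-stimulated genes, against 4.82, 4.82 and 4.83. Colon 4-week replicate 2 had a mean of 4.88 for interferon and cytokine receptors, against 4.76, 4.77 and 4.78.

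The age effect differed between colon and small intestine by the list test for 8 lists, with these medians of the difference and with no gene called over all genes. Enteroendocrine genes had -0.84 (adjusted p = 0.00602, adjusted p = 0.769 with an estimated correlation), lost without small-intestine 4-week replicate 2 (0.154), 8-week replicate 2 (0.110) or colon 8-week replicate 2 (0.0974). Interferon-stimulated genes had 0.23 (adjusted p = 0.00330, adjusted p = 0.902 with an estimated correlation), lost without small-intestine 8-week replicate 1 (0.0818) and pointing down without colon 4-week replicate 2 (0.0399). MHC class II genes had 0.67 (adjusted p = 0.00330, adjusted p = 0.886 with an estimated correlation), lost without small-intestine 4-week replicate 2 (0.0788) or colon 4-week or 8-week replicate 2 (0.362 and 0.315). Cholesterol genes had 0.41 (adjusted p = 0.00294, adjusted p = 0.809 with an estimated correlation), lost without small-intestine 4-week replicate 1 (0.122), 8-week replicate 2 (0.232) or colon 8-week replicate 1 (0.0925). T cell genes had 0.92 (adjusted p = 1.52e-04, adjusted p = 0.549 with an estimated correlation). Immediate early genes had -0.96 (adjusted p = 0.00330, adjusted p = 0.809 with an estimated correlation), 4 lower adjusted over the list alone, lost without small-intestine replicate 2 at 4 or 8 weeks (0.0546 and 0.161) or colon replicate 1 at 4 or 8 weeks (0.156 and 0.0589). Mitochondrially encoded genes had 1.34 (adjusted p = 2.14e-07, adjusted p = 0.549 with an estimated correlation), 7 higher adjusted over the list alone. Sex-linked genes had -4.21 (adjusted p = 2.98e-07, adjusted p = 0.549 with an estimated correlation), 4 lower adjusted over the list alone.

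Y-linked genes were low in both 8-week colon libraries. Small intestine under a colon label is argued against by the brush border list, whose mean was 2.97 log2 CPM there, 2.83 in 4-week colon and 9.52 in small intestine, and lower depth by a ratio of total counts of 1.07. Female mice in that group remain open: the 4 X-linked partners had a mean log2 fold change of 0.39 (Eif2s3x 0.93, Kdm5c 0.38, Kdm6a 0.20, Ddx3x 0.06), which is consistent with that explanation, although none passed alone. Kdm5d kept 23.9% of its level, and sex is not a group of the design, so that age and any sex difference overlap in colon. No separate test was made of a biological explanation from the design. In small intestine Ddx3y and Eif2s3y had age log2 fold changes of -0.17 (SE 0.44) and -0.52 (SE 0.52). Kdm5d and Uty had -0.25 (SE 0.23) and -0.45 (SE 0.41). These values argue against a fall with age of the colon's size in both tissues. An age difference limited to colon was not tested, and the design cannot tell it apart from a difference in the sex of the mice.

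Lars2 took a larger share of the counts in small intestine. A coordinated rise of mitochondrial aminoacyl-tRNA synthetases is argued against by the 16 others, with a median log2 fold change of 0.37 (-0.29 to 1.46), 4 higher and 0 lower in colon. Reads shared with other transcripts cannot be told apart from a change in Lars2: 1 tested gene, AA474408, shares a stretch of 63 bases at 95.2% identity and had -3.46 (SE 0.41), with -5.36 from the 4-week libraries alone and -1.55 from the 8-week libraries alone, where its call was lost (adjusted p = 0.0826), but 3 genes were needed. The longest and closest match, 72 bases at 98.6% identity with Gm15564, is a gene not in the count table used here, so that its reads may be counted in Lars2 and the Lars2 share may not measure Lars2 transcripts alone. A test of Lars2 transcripts with and without the stretch could not be made, since the index holds 1 Lars2 transcript. The tissue difference itself stays open, untested.

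The T cell and intraepithelial lymphocyte list passed its test toward 8 weeks with the preset correlation and not with an estimated one (adjusted p = 0.630 in small intestine, 0.144 in colon and 0.212 over both), and over both tissues 3 of its 21 genes were called higher. A carry-over of lamina propria that brings stromal cells is argued against. The age effect on the T cell list (1.40, SE 0.20) exceeded that on the stromal list (-0.66, SE 0.31) by 2.06 (SE 0.33). Myeloid genes had 0.31 (SE 0.25), for a difference of 1.08 (SE 0.38). B cell genes had 1.01 (SE 0.51), for a difference of only 0.39 (SE 0.50), so that carry-over of lymphoid cells without stroma may remain. None of the 21 list genes is in another list. A sex difference cannot be told apart from age in colon. In small intestine, where Y-linked genes were present at both ages, the median was 1.18, with 18 of 21 genes positive and none called over all genes. The test also asked for a pass with an estimated correlation there. No list reached one in any comparison, so that this requirement could not decide. Age, which the design names, stays open and untested apart from these.

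Chance was examined with other splits into 4 and 4. For tissue, 1 of 35 splits called as many genes, the real one, with 4891 against at most 0 in the others. Group was the only term, so that every other split left the tissue difference in the residual spread, where few calls can be made. The share of 1 in 35 is also the smallest possible, so that these splits cannot exclude chance for tissue. For age with tissue as a term the real split called 0 genes, so that each of the 34 splits necessarily called as many, and the highest other called 17. This leaves chance not excluded and does not bear on the 7 genes called over both tissues, which came from the model with 4 groups. That split set small-intestine 8-week replicate 2, colon 4-week replicate 2 and both 8-week colon libraries against the rest. A split calling more than the real one points to some structure of the libraries, but 3 of the 4 libraries on that side are from 8 weeks, so that its 17 genes cannot be told apart from an effect of age.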

How the results depend on the processing

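Robust empirical Bayes, the nuclear protein-coding genes, the single-age contrasts, the crossed block, the fits without the 8-week colon libraries and the list tests that left out a library were chosen after the results were seen. Genes past the threshold for tissue (5137) stayed within 1.5 times under all other settings and fell to 2908 without the 8-week colon libraries, 3028 with 4-week and 2767 with 8-week libraries alone, where fewer libraries enter; leaving out 1 library gave 3645 to 4860. The age counts moved more, and where the setting does not itself change the genes or libraries tested the cause was not tested. In small intestine the count of 1 became 74 (DESeq2), 3 (limma-voom), 315 (no low-count filter), 2 (replicate number as block), 2 (that tissue alone), 0 (robust empirical Bayes) and 2 (nuclear protein-coding genes), and 0 to 16 leaving out 1 library. In colon the count of 9 became 140 (DESeq2), 18 (limma-voom), 326 (no filter), 2 (length-scaled counts) and 0 (that tissue alone), and 8 to 32. Over both, the count of 7 became 1 (RLE), 213 (DESeq2), 13 (limma-voom), 494 (no filter), 1 (length-scaled), 2 (number block), 0 (additive model), 24 (robust) and 22 (nuclear protein-coding), and 0 to 44. The interaction count of 0 became 65 (DESeq2), 283 (no filter) and 1 (crossed block), and 0 to 7. Of 47 list calls 0 held with an estimated correlation, and 40 to 60 were made leaving out 1 library. The correlation of age effects was 0.188 at 10 CPM or more, against 0.0704.

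Kdm5d reversed for tissue to 0.25 without the 8-week colon libraries and to 0.13 with the 4-week libraries alone. The interferon-stimulated list reversed without colon 4-week replicate 2, in colon (adjusted p = 5.41e-06, lowest 2.67e-29 and highest 0.943 over its 10 alternatives, and 0.0508 without colon 8-week replicate 2) and in the interaction (adjusted p = 0.0399, 3.86e-25 to 0.902, and 0.0818 without small-intestine 8-week replicate 1); the cause was not tested. Named genes otherwise kept direction and side of the threshold in 2810 values and lost the call in 185; lists did so in 377 and 91.

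Replicate numbers were not shown to pair libraries: replicate differences correlated between groups across 10499 genes at -0.107 to 0.143. At 8 weeks the 4 Y-linked genes were lower in both colon libraries than in both small-intestine libraries. Eif2s3y measured 3.94 and 0.817 CPM against 152 and 74.6 CPM. Unless Y-linked genes fell with age in colon alone, these levels argue against the same mice for both tissues at 8 weeks. Pairs of both tissues may therefore not hold there. Numbers as pairs of both tissues gave 4440 tissue genes and 0 interaction genes, as a block 4951, 7 in colon and 0, and crossed at 4 weeks 5133. In simulated data 14% of changes of 2-fold and 86 to 90% of 4-fold were recovered for age within a tissue. For tissue the shares were 54% and 96%, and for the interaction 6% and 50%. Beside 200 changed genes, false calls came to 12 for tissue, 6 in small intestine, 9 in colon, 11 over both and 3 for the interaction. Only genes of at least 5 CPM were changed, each gene was given the spread of the trend, and all other genes had the same level in both tissues. Recovery may be lower in the real data, so that not only small changes can be missed. In small intestine the fitted age changes of Slc40a1 and Trpv6 were larger than 4-fold and were not called. A lone library left in a group is assumed to vary like the other groups.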

Other observations

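The families described here were chosen after the tissue contrast was seen, and no test of an explanation is reported in this part. Over all genes 5137 of 15844 were called for tissue, 2754 higher and 2383 lower. Family counts were not tested against that share. All 4 tested gasdermin C genes were higher in colon, Gsdmc2 by a log2 fold change of 4.09 (SE 0.30) and Gsdmc4 by 3.39 (SE 0.26), with reads shared among the copies. Of 14 carbonic anhydrase genes 6 were higher and 0 lower, among them Car2, which measured 39.8 ± 13.6 CPM in small intestine and 1097 ± 228 CPM in colon (n = 4 each), and Car12 at 3.27 (SE 0.25). Of 19 fucosyl- and sialyltransferase genes, counted by identifier with St6galnac2 present under 2 identifiers and not called under either, 9 were higher and 1 lower; St6galnac6, which adds sialic acid to glycans, measured 2.13 ± 1.40 and 424 ± 32.9 CPM, Fut2 rose by 4.09 (SE 0.29) and St3gal4 fell by 2.56 on the log2 scale (SE 0.18). Of 10 mucin genes 5 were higher and 1 lower, the latter Muc13 at -1.03 (SE 0.21), and of 15 keratin genes 6 were higher and 1 lower, with Krt8 and Krt19 at 1.39 (SE 0.23) and 1.44 (SE 0.22).

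Of 7 aquaporin genes 2 were higher and 3 lower in colon, Aqp4 at 4.55 (SE 0.24) against Aqp3 at -6.02 (SE 0.80) and Aqp7 at -4.97 (SE 0.49). The ligands of the guanylate cyclase receptor parted, Guca2a at 3.86 (SE 0.20) and Guca2b at -3.62 (SE 0.39), while the receptor gene Gucy2c was not called (-0.14, SE 0.14). Of 9 claudin genes 2 were higher and 1 lower, Cldn8 rising from 0.398 ± 0.278 to 52.8 ± 10.3 CPM. Of 14 UDP-glucuronosyltransferase genes 3 were higher and 4 lower, with Ugt2b5 at 2.29 (SE 0.31) and Ugt2a3 at -10.50 (SE 0.59). Of 4 small proline-rich genes 2 were higher and 0 lower. Of 15 chemokine genes 2 were higher and 3 lower, with Ccl28 at 1.03 (SE 0.15) and Ccl25 at -2.98 (SE 0.25); under RLE scaling 4 were lower, and the counts of the other families named here were the same.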
